A study of Mus musculus with 4 samples.

How the data were processed

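Polyadenylated RNA of C2C12 cells was broken by heat, copied from random primers and sequenced as paired ends, per the labels' protocols, with 1 library for each of 4 time points (-24, 60, 120 and 168 h from the serum switch). The authors deposited the assembled transcripts of each library with their RPKM, a value per kilobase scaled to library size, and each line of the files names Cufflinks. Cufflinks 0.8.0 and TopHat 1.0.13 are named in the submitters' processing notes, with no role or order. The genome build is not given in the sources used here, and coordinates are printed as the files give them. The deposited score column, 1000 for every gene with 1 transcript, was not used. In genes with 1 transcript, the deposited confidence limits lie 2 square roots of a fragment count away from each value. In genes with more transcripts they can lie farther away. That rule gave each library's size from genes with 1 transcript, 28513976, 48228892, 24488680 and 43845266 fragments in growth and at 60 h, 120 h and 168 h. The implied counts of low transcripts were whole within 0.01 for 93.9%, 94.0%, 93.3% and 94.0% of values. The deposited values are called FPKM here, since they count fragments. Assembled transcripts took 86.9%, 88.8%, 88.5% and 89.7% of each library. The median distance to the limit was 11.6%, 10.2%, 14.3% and 11.1% of a gene's value, so the 120 h library is the least precise.

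Gene names came from a GENCODE mouse annotation. Its build can differ from that of the files, so no coordinate of one was used with the other. Runs of intron, exon and intron lengths named 122077 of 137305 introns. A further 5294 were named by their own length between named neighbours, of which 2.98% would match by chance. In all 12822 genes were named. A single-exon transcript was counted to a gene where at least 50% of it lay within that gene's assembled exons. Genes with a single exon were not analysed here. The labels' protocols describe no marking of strand, so fragments of overlapping genes on opposite strands cannot be separated. Copies were sought as the percent of a gene's sampled words of 50 bases that also occur in transcripts of another annotated gene.

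The main gene value was the sum of FPKM over a gene's assembled transcripts, with distances to the limits added in quadrature and unassembled genes taken as 0. With 1 library per time point no test was possible, so a size rule was used: at least 2-fold on the log2(FPKM + 1) scale, at least 1 FPKM in the higher library and intervals that do not overlap. No fold is given against a library in which the gene was not assembled. The 4 comparisons were 60 h against growth, 120 h against 60 h, 168 h against 120 h and 168 h against growth. There were 21 gene lists. They covered myogenic regulators, inhibitors of differentiation, sarcomere, excitation-contraction coupling and neuromuscular junction, muscle energy metabolism, fusion and adhesion, cell cycle, cell cycle exit, extracellular matrix, serum and growth response, insulin-like growth factor axis, splicing regulators, cytoplasmic ribosomal proteins, proteasome and heat shock, interferon response, isoform genes, and markers of smooth muscle, cardiac, adipocyte, osteoblast and chondrocyte, and macrophage and endothelial cells. A list's median log2 ratio is given as its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries. An isoform switch was a change of at least 30 percentage points in the share of 1 intron chain, with share intervals apart, in genes with at least 5 FPKM in both libraries. First exon switches used the first splice donor in the same way.

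These rules, the lists and their alternatives were fixed before the data were examined. Genes to be named were protein-coding genes with at least 10 FPKM in the higher library and the 10 largest ratios in each direction at the first step and 5 at each later step. Added to them were the 4 members of each list with the largest ratio at the first step, and the 10 largest isoform and first exon switches overall and within the isoform list. Some genes that this rule takes are not reported here. Alternatives fixed beforehand were a pseudocount of 0.1, no minimum or a minimum of 5 FPKM, 2 scalings, multi-exon transcripts alone, loci without the annotation, a 4-fold rule and stricter limits on switches. Chosen after seeing the data were 2 other gene measures, fragments over the union of a gene's exons and the FPKM through the introns. The FPKM through the introns is the median over a gene's introns of the FPKM of all transcripts that hold each intron. It is set beside the sum in the text because a sum of FPKM can count a gene broken into pieces more than once. Also chosen after seeing the data were the restriction to genes assembled in both libraries, the choice at a shared splice site, the count of genes with 1 library apart, equal totals for the lists and 8 further gene lists.

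The rules were tested on simulated data, with 200 genes changed among 10407, 10855, 10795 and 10407 in the 4 comparisons in the order given. Changes of 3-fold were found in 90%, 87%, 88% and 92% of genes and changes of 5-fold in 98%, 97%, 94% and 100%, with 0 in the wrong direction and 2, 0, 0 and 0 unchanged genes called. Exchanged isoforms were found in 98.9%, 99.0%, 98.6% and 99.4% of 1000 genes. The simulations hold counting error and no errors of assembly. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.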

Results

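Polyadenylated RNA from C2C12 cells was sequenced as paired ends in 4 libraries. C2C12 is a mouse skeletal myoblast line that stops dividing and fuses into myotubes when serum is lowered. The time points were -24 h, during exponential growth in high serum, and 60 h, 120 h and 168 h after the switch to low serum, with 1 library at each. In that order the libraries held 28513976, 48228892, 24488680 and 43845266 fragments, so the 120 h library was the shallowest. There were no replicates, so each difference below is between 2 libraries, with no replicate check and no p-value. Expression is given in FPKM, fragments per kilobase of transcript scaled to library size, and ± is the distance from a value to its confidence limit. That distance covers no variation between cultures. It is counting error alone in genes with 1 transcript and can be wider in genes with more transcripts. A gene is said to have risen or fallen where the libraries differed at least 2-fold on the log2(FPKM + 1) scale, the higher had at least 1 FPKM and the intervals did not overlap. That scale understates the change of low genes. Unless stated otherwise, values are FPKM summed over a gene's transcripts, and a call by both measures also holds for the FPKM through the gene's introns. A gene not assembled in 1 library mostly lacks a value there by either measure, so its calls agree largely by construction. Percentiles place a list's median among 10000 random lists of matched expression.

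The comparison of 60 h with growth asks what changed once growing myoblasts were moved to differentiation medium. Of the sarcomere genes, which encode the contractile apparatus, 44 of 49 rose and 0 fell, 41 and 0 by both measures (median log2 ratio 4.04, percentile 100). Acta1, the skeletal alpha-actin gene (chromosome 8, 126415661 to 126418727), rose from 18.4 ± 1.34 to 5150.4 ± 16.7 FPKM. Myl4, an embryonic myosin light chain gene, rose from 2.05 ± 0.466 to 1361 ± 8.20 FPKM. Tnnt1, the slow troponin T gene, was not assembled in growth and had 510.0 ± 17.0 FPKM at 60 h. Actc1, the cardiac alpha-actin gene, rose from 6.92 ± 0.841 to 1758 ± 9.51 FPKM. Of the cell cycle genes 0 of 40 rose and 35 fell, 0 and 34 by both measures (median log2 ratio -1.64, percentile 0).

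Of the genes of excitation-contraction coupling and the neuromuscular junction, 22 of 28 rose and 1 fell at 60 h (median log2 ratio 2.5, percentile 100). Atp2a1, the calcium pump of fast fibres, rose from 2.57 ± 0.450 to 771 ± 13.4 FPKM. Casq2, a calsequestrin gene, rose from 1.87 ± 1.03 to 235 ± 2.55 FPKM and Cav3, the muscle caveolin gene, from 2.28 ± 0.805 to 203 ± 5.47. Jsrp1 was not assembled in growth and had 118 ± 8.22 FPKM at 60 h. Of muscle energy metabolism genes 14 of 19 rose and 0 fell (median log2 ratio 1.56, percentile 100). Ckm, the muscle creatine kinase gene, rose from 1.99 ± 1.06 to 729 ± 5.88 FPKM, Cox6a2 from 1.70 ± 0.642 to 442 ± 7.02 and Mb, the myoglobin gene, from 1.95 ± 0.536 to 308 ± 3.49. Cox8b was not assembled in growth and had 75.7 ± 2.70 FPKM. Of fusion and adhesion genes 5 of 19 rose and 1 fell (median log2 ratio 0.28, percentile 99.1), with 3 falling at a pseudocount of 0.1 FPKM and 2 over the union of exons. Mymk and Mymx, which encode membrane proteins of myoblast fusion, rose from 2.60 ± 0.524 to 839.6 ± 13.8 FPKM and from 0.886 ± 0.396 to 85.1 ± 7.71 FPKM. Ncam1 rose from 49.4 ± 4.20 to 238 ± 8.82 FPKM and Itga7, an integrin gene, from 61.0 ± 4.47 to 278 ± 5.32.

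Of the myogenic regulators 5 of 14 rose and 1 fell at 60 h (median log2 ratio 0.37, percentile 98.7), and 7 rose and 0 fell through the introns. Myog, the gene of the differentiation factor myogenin, rose from 16.9 ± 1.27 to 399 ± 3.08 FPKM and Mef2c from 5.04 ± 1.22 to 24.5 ± 2.35. Tead4 rose from 9.30 ± 1.43 to 34.2 ± 2.47 FPKM and Myf6 from 0.315 ± 0.364 to 2.83 ± 0.463. Of the inhibitors of differentiation 3 of 12 rose and 4 fell (median log2 ratio -0.50, percentile 11.9). Id3 (chromosome 4, 135699702 to 135701404), whose protein blocks basic helix-loop-helix factors, fell from 534 ± 8.31 to 9.59 ± 0.928 FPKM, Id1 from 291 ± 6.72 to 23.0 ± 1.36 and Id2 from 92.0 ± 3.64 to 10.5 ± 1.41. Bhlhe40 rose from 14.6 ± 0.847 to 84.4 ± 1.56 FPKM. Of cell cycle exit genes 5 of 12 rose and 1 fell (median log2 ratio 0.43, percentile 99.2). Cdkn1a, which encodes an inhibitor of cyclin-dependent kinases, rose from 189 ± 4.41 to 1354 ± 10.3 FPKM and Gadd45a from 10.8 ± 1.17 to 203 ± 3.78. Ccng2 rose from 3.83 ± 0.474 to 12.5 ± 0.676 FPKM and Ccnd3 from 54.3 ± 1.67 to 146 ± 2.52. In the cell cycle list, Ccne1 fell from 49.6 ± 1.91 to 5.39 ± 0.486 FPKM and Rrm2, a ribonucleotide reductase gene, from 353 ± 6.06 to 47.1 ± 2.06. Mcm5, of the replicative helicase, fell from 162 ± 2.82 to 23.1 ± 0.835 FPKM and Ccnd1 from 163 ± 2.44 to 26.1 ± 0.757.

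Of serum and growth response genes 0 of 18 rose and 10 fell at 60 h (median log2 ratio -1.16, percentile 0). Hmga2 fell from 38.8 ± 1.47 to 4.24 ± 0.675 FPKM. Fosl1 fell from 65.8 ± 7.26 to 8.39 ± 0.595 FPKM and Ccn1 from 218 ± 3.92 to 34.1 ± 1.19. Of extracellular matrix genes 15 of 34 rose and 4 fell (median log2 ratio 0.26, percentile 99.8). The collagen genes Col6a1, Col6a2 and Col1a1 rose from 3.55 ± 0.456 to 185 ± 3.11, from 2.31 ± 1.34 to 85.3 ± 2.11 and from 7.37 ± 1.67 to 142 ± 3.72 FPKM. Dcn, the decorin gene, was not assembled in growth and had 9.04 ± 0.649 FPKM. Of the insulin-like growth factor axis 4 of 15 rose and 3 fell (median log2 ratio 0.37, percentile 98.5), and the median was -0.01 without members under 1 FPKM in both libraries. Through the introns 8 rose and 2 fell, with a median of 1.25, and over the union of exons 7 and 2, with a median of 0.53. The noncoding RNA H19 rose from 1728 ± 29.6 to 9152 ± 94.8 FPKM, Igfbp5 from 58.9 ± 1.19 to 534 ± 2.72 and Fst from 6.70 ± 1.12 to 51.6 ± 1.84. Igf2 rose from 7.04 ± 1.5 to 167 ± 1.93 FPKM, an uncertain value because 61.0% of its sampled words of 50 bases also occur in another annotated gene.

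Of the splicing regulators 3 of 26 rose and 6 fell at 60 h (median log2 ratio 0.03, percentile 93.1), and the median was -0.28 through the introns and -0.31 over the union of exons. After median-ratio rescaling 5 rose and 5 fell. Rbm24 rose from 0.80 ± 0.447 to 25.5 ± 1.38 FPKM and Rbfox1 from 0.399 ± 0.564 to 6.83 ± 0.816. Srsf7 fell from 147 ± 13.2 to 44.1 ± 6.21 FPKM, and Mbnl3 had 6.61 ± 1.72 FPKM in growth and was not assembled at 60 h. Of proteasome and heat shock genes 8 of 22 rose and 4 fell, 8 and 1 by both measures (median log2 ratio 0.05, percentile 92.3). Through the introns the median of this list was 0.48, at percentile 100.0. Trib3 rose from 21.1 ± 1.2 to 194 ± 2.68 FPKM, Atf3 from 3.64 ± 1.84 to 41.5 ± 1.35 and Hspb7 from 1.09 ± 0.632 to 29.3 ± 1.12. Trim63, a muscle ubiquitin ligase gene, was not assembled in growth and had 40.6 ± 1.82 FPKM. Of interferon response genes 3 of 14 rose and 1 fell (median log2 ratio -0.19, percentile 29.1), with a median of 0.54 through the introns and 0.46 over the union of exons. With equal totals 5 rose and 1 fell. Isg15 rose from 0.886 ± 0.560 to 6.04 ± 0.832 FPKM. Of cytoplasmic ribosomal protein genes 6 of 30 rose and 6 fell (median log2 ratio -0.32, percentile 26.8). Over the union of exons their median was -0.52, at percentile 0.720. These are uncertain because such genes have near-identical copies. Rps20, with 9.88% of its words in other genes, had 181 ± 4.76 FPKM at 60 h and was not assembled in growth.

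Markers of other lineages moved in different directions at 60 h. Of smooth muscle markers 3 of 10 rose and 4 fell (median log2 ratio 0.05, percentile 72.4). Tagln (chromosome 9, 45736590 to 45744195) fell from 700.1 ± 17.3 to 52.2 ± 1.39 FPKM, Actg2 from 251 ± 5.08 to 47.3 ± 1.70 and Cnn1 from 43.5 ± 2.03 to 5.68 ± 0.567. Smtn rose from 30.7 ± 1.14 to 109.8 ± 4.71 FPKM by the sum and was not called through the introns or over the union of exons. Of osteoblast and chondrocyte markers 0 of 5 rose and 4 fell (median log2 ratio -1.72, percentile 0.0150). Spp1, the osteopontin gene, fell from 985 ± 8.69 to 298 ± 7.73 FPKM, with 11.2% of its words in other genes. Runx2 fell from 14.2 ± 2.00 to 3.27 ± 0.312 FPKM and Sp7 from 9.19 ± 2.13 to 1.35 ± 0.684. Of cardiac markers 2 of 6 rose and 1 fell (median log2 ratio -0.66, percentile 9.98, and -0.04 over the union of exons), with Myh6 at 22.2 ± 2.90 FPKM, 19.9% of its words being in other genes. Of adipocyte markers 1 of 3 rose and 1 fell (median log2 ratio -0.29, percentile 44.7), with a median of 1.15 through the introns and 1.16 over the union of exons. Pparg fell from 20.7 ± 3.66 to 3.18 ± 0.636 FPKM, and Cd36 was not assembled in growth and had 4.78 ± 1.44 FPKM. Of macrophage and endothelial markers 3 of 6 rose and 0 fell, 0 and 0 by both measures (median log2 ratio 0.72, percentile 78.6), with Cd68 at 4.15 ± 1.51 and Vwf at 5.34 ± 1.29 FPKM. Over all settings the median of this last list ranged from 0.46 to 2.74.

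Of all 12492 genes compared at 60 h, 1385 rose and 1932 fell, 1039 and 1156 of them by both measures. Of those called by both measures, 514 and 966 had values by each measure in both libraries. The largest ratios among protein-coding genes with at least 10 FPKM that rose were those of Myh13, Myh8, Tnnt1, Myl4, Acta1, Myh4, Ckm, Mymk, Actc1 and Atp2a1. The myosin heavy chain genes Myh13, Myh8 and Myh4 had 817 ± 17.4, 945 ± 21.1 and 255 ± 11.2 FPKM at 60 h. Their values are uncertain, with 8.66%, 12.9% and 21.5% of their words in other genes and no value through the introns of Myh8 and Myh4 at 60 h. Among the genes that fell, Ndufa5 had 113 ± 5.70 FPKM in growth and Ahnak2 48.2 ± 3.20, and neither was assembled at 60 h. Ndufa5 was again assembled at 120 h, with 109.8 ± 10 FPKM. Ahnak2 had 8.13 FPKM through the introns in growth and was again assembled at 168 h, with 20.8 ± 0.956 FPKM by the sum and 20.8 through the introns, so from growth to 168 h it fell by the sum and rose through the introns. Prl2c3, Rpl36al and Rpl18 had 194 ± 39.2, 99.0 ± 24.0 and 74.5 ± 4.90 FPKM in growth and were not assembled at 60 h. They are uncertain, with 55.6%, 14.3% and 9.06% of their words in other genes, and had 55.8, 30.3 and 37.2 FPKM in growth through the introns. Tnfrsf12a, Mta2 and Apc2 had 340.0 ± 7.06, 82.8 ± 1.91 and 137 ± 24.9 FPKM in growth and no transcript of their own at 60 h. Their introns then carried 47.9, 29.7 and 108 FPKM in transcripts assigned to other genes. Tnfrsf12a and Mta2 also fell through the introns, and Apc2, from 137 FPKM, did not pass the rule there. The name Apc2 is uncertain for these transcripts. Their span, 79755245 to 79756861 on chromosome 10, starts beside the first splice donor of the ribosomal protein gene Rps15, at 79755229. The median log2 ratio of all genes, -0.25, was -0.04 after median-ratio rescaling, and the share of higher calls went from 41.8% to 55.7%. That share was 53.6% through the introns and 52.3% over the union of exons. Median-ratio rescaling centres the ratios between libraries, so it nearly removes the all-gene median by construction. Among genes assembled in both libraries 865 rose, among loci built without the annotation 2279 rose, and over the union of exons 1283 genes fell. Over all settings the medians ranged from 4.04 to 5.52 for the sarcomere, from 2.5 to 3.47 for excitation-contraction coupling and from 1.56 to 3.99 for muscle energy metabolism.

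Some named genes had a value through the introns under the sum by more than 1.5 times at 60 h or in growth. At 60 h Cav3, Mymx, Ncam1, Col6a1, Col6a2, Myh13, Myl1, Myh6, Smtn, Trim63, Id2, Rbfox1, Pparg, Sp7, Cd68 and Vwf had 102, 26.3, 145, 94.6, 42.3, 165, 98.8, 13.7, 39.7, 25.3, 3.77, 3.01, 2.03, 0.389, 0.692 and 0.525 FPKM through the introns. In growth Rrm2, Hmga2, Pparg, Runx2, Tead4, Mbnl3, Atf3, Atp2a1, Cav3, Mef2c and Lpl had 176, 17.3, 13, 6.37, 5.29, 2.62, 1.62, 1.33, 1.14, 1.0 and 0.725. Casq2, Ckm, Col1a1, Col6a2, Hspb7 and Igf2 had no value through the introns in growth, nor did Hmga2 at 60 h. Over the union of exons the fall of Runx2 did not pass the rule, with a log2 ratio of -0.87.

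**Figure D1:**
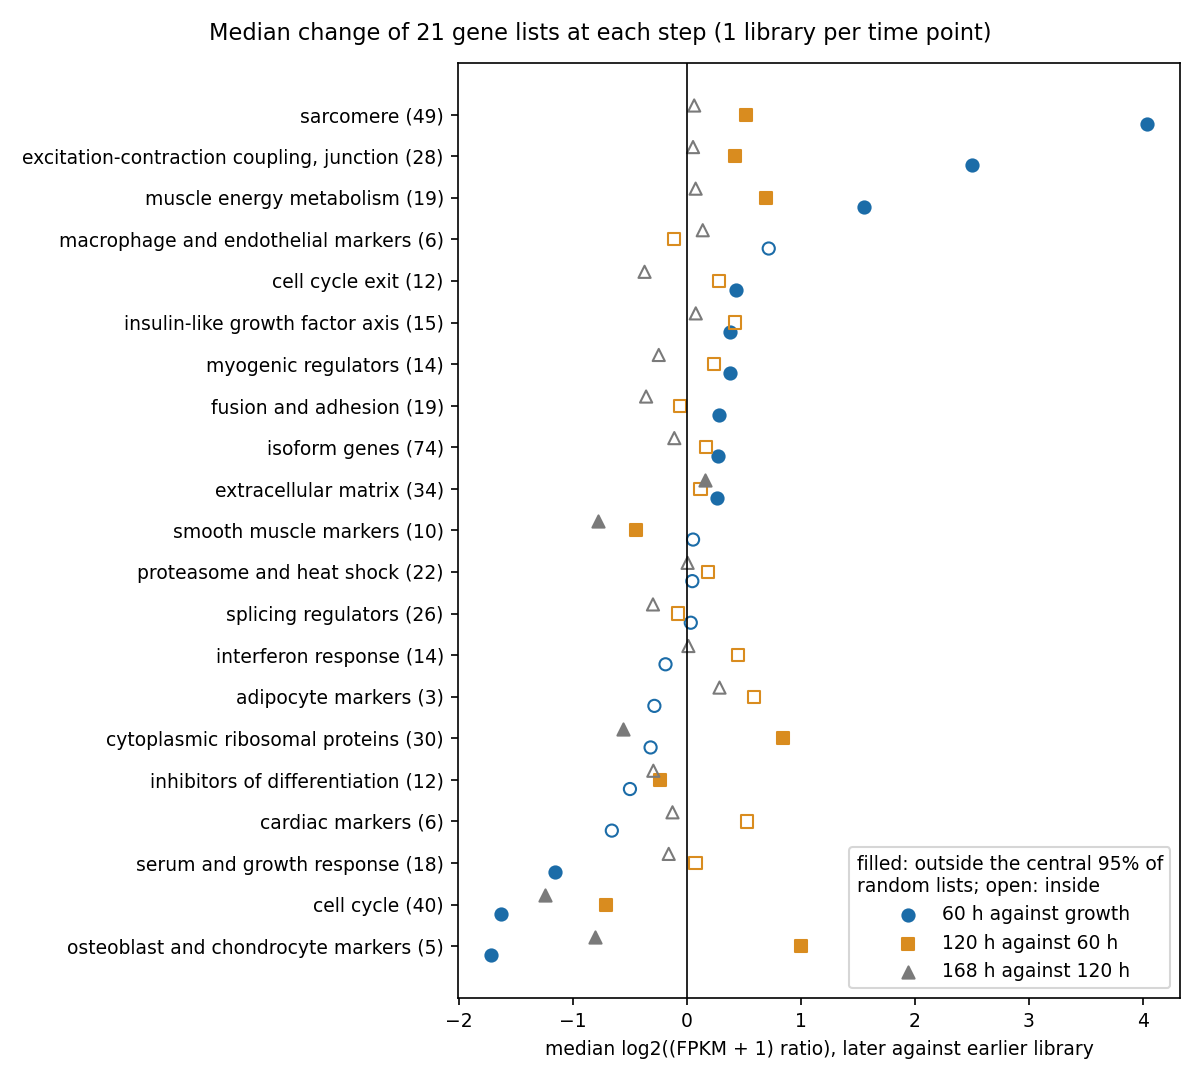
Median log2((FPKM + 1) ratio) of 21 gene lists on the horizontal axis, with circles for 60 h against growth, squares for 120 h against 60 h and triangles for 168 h against 120 h; the number after each list name counts its measured members at 60 h against growth, and filled points lie outside the central 95% of random lists. The sarcomere list has a median of 4.04 at the first step, and the cell cycle list lies below 0 at all 3 steps, at -1.64, -0.71 and -1.25.

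The comparison of 120 h with 60 h follows the cells from early to later differentiation. Of the muscle energy genes 5 of 19 rose and 0 fell, 4 and 0 by both measures (median log2 ratio 0.70, percentile 100.0), and 3 rose under each of median-ratio rescaling, equal totals and the union of exons. Mb rose from 308 ± 3.49 to 621 ± 9.76 FPKM, but its log2 ratio of 1.01 was 0.82, 0.79 and 0.04 in those settings and did not pass the rule. Of the sarcomere genes 8 of 49 rose and 5 fell, 5 and 3 by both measures (median log2 ratio 0.51, percentile 100), while 4 rose and 6 fell after median-ratio rescaling, and 5 and 6 with equal totals. Through the introns 9 rose and 3 fell, and over the union of exons 4 rose and 3 fell. Myh4 and Myh8 fell by the sum, at log2 ratios of -1.90 and -1.74. Both rose through the introns, where they had no value at 60 h, and over the union Myh4 rose and Myh8 was not called. Tnnt3, not assembled at 120 h, is also counted as falling, by both measures. Myl1, a fast light chain gene with 13.2% of its words in other genes, rose from 157 ± 7.75 to 489 ± 24.7 FPKM. Myf6 rose from 2.83 ± 0.463 to 11.8 ± 1.37 FPKM and Hspb7 from 29.3 ± 1.12 to 71.2 ± 2.47. Of cell cycle genes 0 of 40 rose and 6 fell (median log2 ratio -0.71, percentile 0). In this list 13 fell after median-ratio rescaling, 15 with equal totals and 12 over the union of exons, and through the introns 12 fell and 2 rose. Of smooth muscle markers 1 of 9 rose and 3 fell (median log2 ratio -0.45, percentile 0.260). Tagln fell from 52.2 ± 1.39 to 24.6 ± 1.44 FPKM, Actg2 from 47.3 ± 1.70 to 14.4 ± 1.34 and Cnn1 from 5.68 ± 0.567 to 2.02 ± 0.479.

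Of excitation-contraction genes 1 of 29 rose and 0 fell at 120 h (median log2 ratio 0.42, percentile 99.8), and the median was 0.11, at percentile 97.2, over the union of exons. Of inhibitors of differentiation 0 of 12 rose and 1 fell, 0 and 0 by both measures (median log2 ratio -0.24, percentile 0.710), and the percentile was 6.43 through the introns. Of extracellular matrix genes 7 of 34 rose and 0 fell, 3 and 0 by both measures (median log2 ratio 0.12, percentile 43.8), and the list's median was -0.07 and -0.10 under the median-ratio and equal-total scalings. Dcn rose from 9.04 ± 0.649 to 27.1 ± 1.57 FPKM. Lpl, the lipoprotein lipase gene of the adipocyte list, rose from 2.83 ± 0.314 to 21.2 ± 1.86 FPKM. Of ribosomal protein genes, uncertain for their copies, 13 of 31 rose and 6 fell (median log2 ratio 0.84, percentile 100). Of osteoblast and chondrocyte markers 2 of 5 rose and 0 fell, 0 and 0 by both measures (median log2 ratio 1.0, percentile 99.0), and the median was -0.07 through the introns and -0.13 over the union of exons. Without members under 1 FPKM in both libraries it was 0.71, at percentile 92.3. Ftl1, Rplp2, Tmsb10 and Rpl6 had 496 ± 15.4, 304 ± 10.3, 250.3 ± 14.9 and 224 ± 11.4 FPKM at 120 h and were not assembled at 60 h, and Ftl1 had no value through the introns in either. They are uncertain, with 51.6%, 18.9%, 18.6% and 25.5% of their words in other genes. Rnasek, at 153 ± 8.55 FPKM at 120 h with 62.7% of its words in other genes, had no transcript of its own at 60 h, but its introns carried 78.9 FPKM there. Tnnt3, Ccdc124, Tnfaip2 and Dpm3 had 153 ± 5.52, 104.98 ± 3.01, 98.6 ± 1.49 and 65.5 ± 3.81 FPKM at 60 h and were not assembled at 120 h. Rpl8 had 1242 ± 7.79 FPKM at 60 h and 0.365 ± 0.258 at 120 h. Rpl8, Tnnt3, Tnfaip2 and Dpm3 were again assembled at 168 h, so their values at 120 h are uncertain.

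Of all 12505 genes, 1556 rose and 485 fell at 120 h, but 352 and 299 did so by both measures. Only 185 and 62 of these had values by each measure in both libraries, and 132 genes were called in opposite directions. The share of higher calls was 76.2%, against 65.7% after median-ratio rescaling, 60.2% after rescaling to equal totals, 35.3% through the introns and 32.2% over the union of exons. By count, 507 rose and 931 fell through the introns, and 272 rose over the union. The all-gene median of 0.17 became 0.01 after median-ratio rescaling, largely by construction, and -0.02 with equal totals.

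The comparison of 168 h with 120 h covers the last step. Of cell cycle genes 1 of 40 rose and 25 fell, 0 and 20 by both measures (median log2 ratio -1.25, percentile 0), and Mcm5 fell from 16.4 ± 3.22 to 7.46 ± 1.29 FPKM (1.60 at 168 h through the introns). Of extracellular matrix genes 7 of 34 rose and 1 fell, 5 and 1 by both measures (median log2 ratio 0.15, percentile 99.4). The median of this list was 0.11, at percentile 93.7, through the introns and 0.15, at percentile 96.7, over the union of exons. Over the union 4 rose and 1 fell. Col6a1 rose from 137 ± 2.62 to 302 ± 4.77 FPKM, Col6a2 from 55.9 ± 1.85 to 283 ± 4.30 (133 at 168 h through the introns) and Dcn from 27.1 ± 1.57 to 57.7 ± 3.48. Of sarcomere genes 8 of 49 rose and 4 fell (median log2 ratio 0.06, percentile 95.3), and their median was -0.02 through the introns, while over the union 5 rose and 2 fell. Tnnt3, not assembled at 120 h, is among the sarcomere genes counted as rising. Myf6 rose from 11.8 ± 1.37 to 27.0 ± 1.48 FPKM, Cox8b from 110.0 ± 3.55 to 265 ± 6.41 and Ccn1 from 36.9 ± 1.75 to 79.3 ± 1.91. Mymx fell from 106 ± 14.8 to 48.3 ± 5.97 FPKM, and 33.0 and 9.41 were its values through the introns. The calls of Mcm5 and Mymx ended with median-ratio rescaling, at log2 ratios of -0.91 and -0.97, and that of Mcm5 with equal totals, at -0.996. Those of Col6a1 and Cox8b ended over the union of exons, at 0.93 and 0.31. Of smooth muscle markers 0 of 8 rose and 3 fell (median log2 ratio -0.78, percentile 0.470). Tagln fell from 24.6 ± 1.44 to 10 ± 0.924 FPKM and Actg2 from 14.4 ± 1.34 to 3.85 ± 0.517. Of fusion and adhesion genes 0 of 19 rose and 2 fell, 0 and 1 by both measures (median log2 ratio -0.36, percentile 2.86, with percentiles 0.10 through the introns and 0.0600 over the union of exons), and 0 fell after median-ratio rescaling. Of ribosomal protein genes, uncertain for their copies, 5 of 28 rose and 6 fell, 3 and 3 by both measures (median log2 ratio -0.56, percentile 0.010), a median below 0 after one above 0 at 120 h against 60 h, and 2 rose and 4 fell over the union of exons. Of osteoblast and chondrocyte markers 0 of 5 rose and 1 fell, 0 and 0 by both measures (median log2 ratio -0.80, percentile 1.75), but the median was 0.02 over the union of exons and -0.09, at percentile 38.7, through the introns. Its percentile was also inside the central 95% with a pseudocount of 0.1 FPKM, at 5.21, with equal totals, at 3.94, and without members under 1 FPKM in both libraries, at 6.83.

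The largest ratios at 168 h by the same rule were those of Rpl8, Tnnt3, Zbed5, Rpl36al and Tnfaip2. Rpl8 had 0.365 ± 0.258 FPKM at 120 h and 1789 ± 10.8 at 168 h. Tnnt3, Zbed5, Rpl36al and Tnfaip2 had 143 ± 6.44, 133 ± 6.23, 100.4 ± 4.32 and 87.9 ± 1.48 FPKM at 168 h and were not assembled at 120 h. Rpl36al is uncertain for its copies, and Rpl8, Tnnt3, Zbed5 and Tnfaip2 because they had been assembled at 60 h. The lowest ratios were those of Tnnt2, Tmsb10, Rpl14, Rps15a and Rnasek. Tnnt2, the cardiac troponin T gene, had 1228 ± 15.3 FPKM at 120 h and 1.08 ± 0.726 at 168 h, where it had no value through its introns. Its value at 168 h, from 9 fragments, is uncertain, since no later library shows whether it was assembled again. Tnnt2 is among the sarcomere genes counted as falling at this step. Rpl14 had 327 ± 9.62 and 0.324 ± 0.290 FPKM, uncertain with 36.7% of its words in other genes and no value through the introns in either library. Tmsb10, uncertain for its copies, and Rps15a, at 250.3 ± 14.9 and 234 ± 10.5 FPKM at 120 h, were not assembled at 168 h. Rnasek had no transcript of its own at 168 h, but its introns carried 88.6 FPKM in transcripts of other genes. Of all 12433 genes, 511 rose and 1259 fell, 318 and 383 by both measures. Only 81 and 150 of those called by both had values by each measure in both libraries. The share of higher calls was 28.9%, against 38.8% after median-ratio rescaling, 38.9% with equal totals, 56.7% through the introns and 57.1% over the union of exons. Through the introns 812 rose and 621 fell, and over the union 335 fell. The all-gene median went from -0.13 to 0.00 with median-ratio rescaling, again largely by construction.

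**Figure D2:**
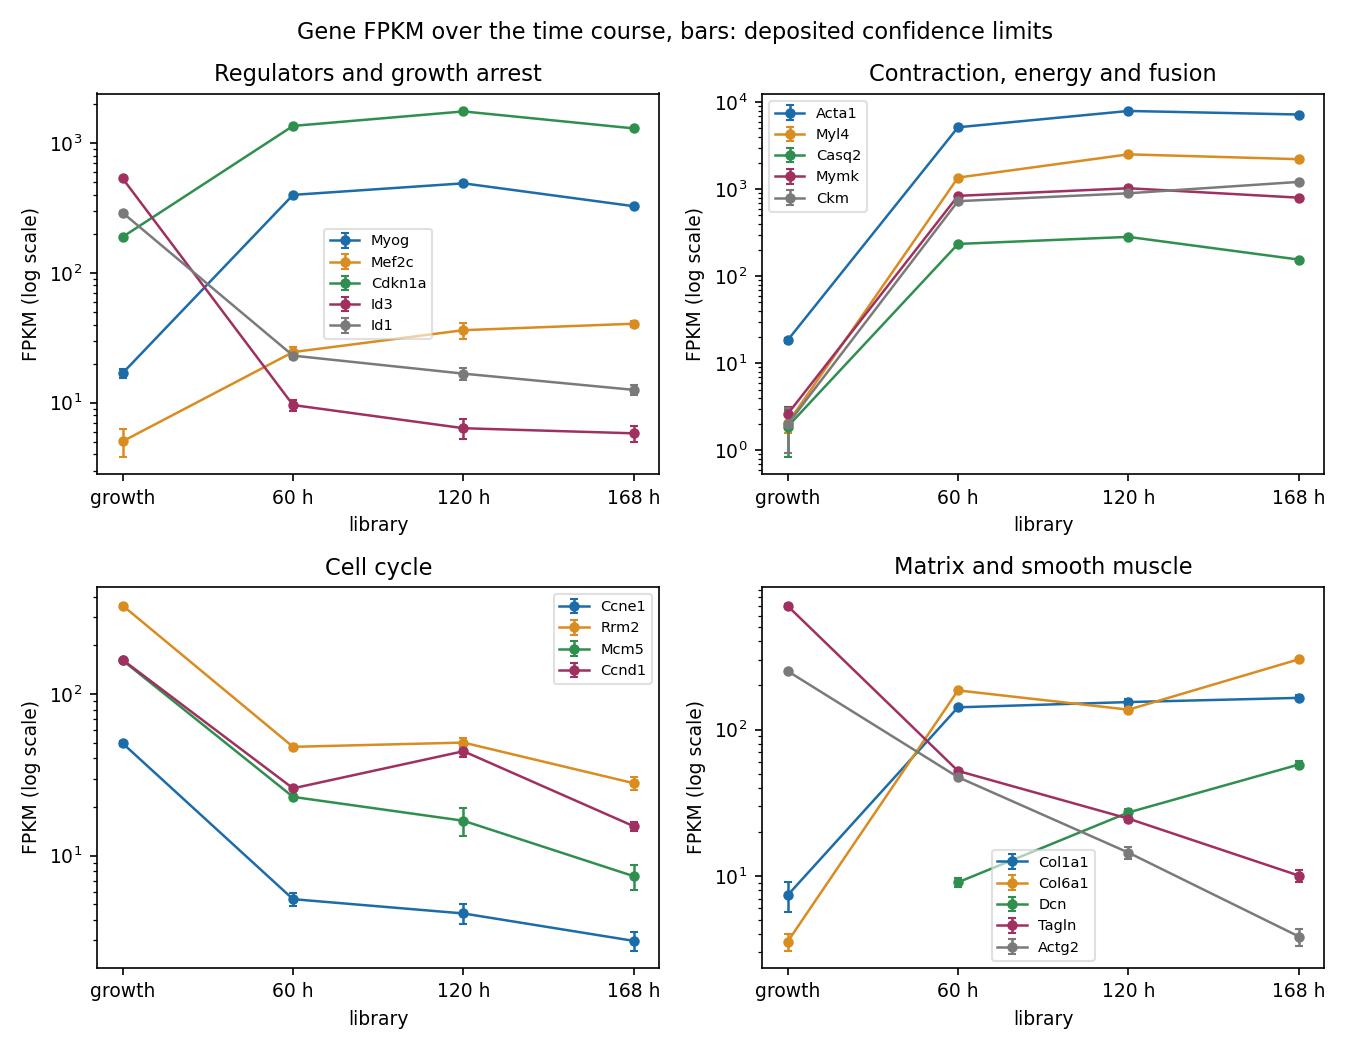
FPKM on a log axis in the growth, 60 h, 120 h and 168 h libraries for regulators, muscle genes, cell cycle genes, and matrix and smooth muscle genes; points are single libraries, bars are the deposited confidence limits added over transcripts, and Dcn has no point in growth, where it was not assembled. Acta1 goes from 18.4 to 5150.4 FPKM between growth and 60 h, and Tagln ends at 10 FPKM at 168 h.

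The comparison of 168 h with growth gives the whole course. Of cell cycle genes 0 of 40 rose and 40 fell, 0 and 40 by both measures (median log2 ratio -3.42, percentile 0). Of sarcomere genes 45 of 49 rose and 1 fell (median log2 ratio 5.36, percentile 100). The gene that fell was Tnnt2, from 124 ± 8.17 FPKM in growth to its uncertain value of 1.08 at 168 h. Of extracellular matrix genes 19 of 34 rose and 3 fell (median log2 ratio 1.36, percentile 100), and Col6a2 rose from 2.31 ± 1.34 to 283 ± 4.30 FPKM. Of splicing regulators 3 of 26 rose and 12 fell, 3 and 10 by both measures (median log2 ratio -0.77, percentile 0.350), and Srsf7 fell from 147 ± 13.2 to 25.8 ± 4.22 FPKM (12.9 at 168 h through the introns). Of muscle energy genes 14 of 19 rose and 0 fell (median log2 ratio 2.90, percentile 100), with Ckm rising from 1.99 ± 1.06 to 1215 ± 8.57 FPKM. Of excitation-contraction genes 24 of 29 rose and 1 fell (median log2 ratio 2.90, percentile 100), with Atp2a1 rising from 2.57 ± 0.450 to 1401 ± 21.4 FPKM. Of inhibitors of differentiation 3 of 12 rose and 6 fell (median log2 ratio -0.93, percentile 0.950), and Id3 fell from 534 ± 8.31 to 5.81 ± 0.785 FPKM. Of cell cycle exit genes 6 of 12 rose and 1 fell (median log2 ratio 1.02, percentile 99.9), against 4 and 2 over the union of exons, and Cdkn1a rose from 189 ± 4.41 to 1295 ± 7.24 FPKM. Of serum and growth response genes 0 of 18 rose and 9 fell (median log2 ratio -1.03, percentile 0.120), and of the insulin-like growth factor axis 6 of 14 rose and 2 fell (median log2 ratio 0.80, percentile 99.8). Of smooth muscle markers 3 of 9 rose and 5 fell, 1 and 4 by both measures (median log2 ratio -1.29, percentile 0.300), and the median was -0.77, at percentile 4.93, over the union of exons. Of the ribosomal protein genes, with the same uncertainty, 9 of 29 rose and 4 fell (median log2 ratio 0.21, percentile 95.02), and the median was -0.24 over the union of exons, where 5 rose and 7 fell. Of adipocyte markers 2 of 4 rose and 1 fell (median log2 ratio 1.95, percentile 99.7). Over all settings the medians ranged from 1.93 to 3.29 for adipocyte and from -2.03 to -0.77 for smooth muscle markers. Lpl rose from 3.67 ± 1.31 to 42.5 ± 1.28 FPKM and Pparg fell from 20.7 ± 3.66 to 1.63 ± 0.277.

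Of all 12500 genes, 1949 rose and 2322 fell between growth and 168 h, 1556 and 1827 by both measures. Of those called by both, 838 and 1396 had values by each measure in both libraries. The share of higher calls was 45.6%, and 55.0% after median-ratio rescaling, which largely by construction moved the all-gene median from -0.18 to -0.00335. Over all settings the medians ranged from 4.94 to 6.18 for the sarcomere, from 2.84 to 3.89 for excitation-contraction coupling, from 2.90 to 5.28 for muscle energy metabolism and from -4.08 to -3.23 for the cell cycle. Of 5137 genes that passed the rule at any of the 3 steps, 1154 fell and 970 rose at the first step alone. More rose than fell under the other settings: 811 fell and 1262 rose after median-ratio rescaling, 949 and 1227 through the introns, 996 and 1171 over the union of exons and 212 and 447 by a 4-fold rule. Among 8625 genes assembled in every library, growth stood apart from the other 3 libraries through the introns in 1154 genes, 650 higher and 504 lower. The 60 h, 120 h and 168 h libraries stood apart in 33, 31 and 147 genes. By the sum, among genes with a value in all 4 libraries, the 60 h and 120 h libraries stood apart in 129 and 123 genes.

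In growth and at 60 h, 120 h and 168 h the assemblies held 72578, 82509, 63606 and 74931 transcripts, of which 72.5%, 72.2%, 66.6% and 69.9% had a single exon. Multi-exon transcripts named 10909, 11937, 11330 and 11780 genes, and 45.1%, 44.2%, 40.1% and 42.0% of them had exactly the introns of an annotated transcript. Over the 4 libraries there were 48288 intron chains, that is, ordered sets of introns. Of these 60.3% occurred in 1 library and 15.3% in all 4. With a chain contained in a longer one counted as the same, 32.7% occurred in 1 library and 27.3% in all 4. Of the chains in 1 library 9.64% were annotated, and of those in all 4 libraries 81.0%.

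The series names switching among isoforms, so the shares of intron chains within genes were compared. Of 75 genes listed beforehand for isoform changes, 74 were measured at 60 h against growth, where 19 rose and 12 fell (median log2 ratio 0.27, percentile 100), and 22 rose and 6 fell over the union of exons. Of the 59 with enough expression, 34 changed a chain's share by at least 30 percentage points. In this list 29 of 64 genes did so at 120 h against 60 h, 28 of 64 at 168 h against 120 h and 41 of 59 at 168 h against growth. At 168 h against growth 26 genes of the list rose and 12 fell (median log2 ratio 0.27, percentile 99.8), but the median was -0.06 through the introns. In Tpm1, the alpha-tropomyosin gene, the intron from 66871249 to 66878835 on chromosome 9 held 100% ± 1.87 of the FPKM at its splice donor, which alternative introns share, in growth. The genes that follow also share a donor. That share was 14.7% ± 0.384 at 60 h, 6.47% ± 0.396 at 120 h and 4.80% ± 0.283 at 168 h. In Tpm2, the beta-tropomyosin gene, the intron from 43528876 to 43531101 on chromosome 4 went from 27.6% ± 2.53 in growth to 89.9% ± 0.509, 100% ± 0.702 and 100% ± 0.533. In Mef2d, a myogenic transcription factor gene, the intron from 87965304 to 87965702 on chromosome 3 held 0% in growth and 62.5% ± 4.29, 44.8% ± 2.97 and 55.3% ± 1.98 later. In Bin1, a membrane tubule gene, the intron from 32581615 to 32582895 on chromosome 18 held 0% in growth and 57.5% ± 2.78, 79.0% ± 5.95 and 59.4% ± 5.49 later. In Rbfox2, a splicing factor gene, the intron from 76924921 to 76928369 on chromosome 15 held 100% ± 3.76 in growth and 30.5% ± 6.53 at 168 h. In Naca the intron from 127473617 to 127483223 on chromosome 10 held 100% ± 11.8 in growth and 0% at 168 h. Tpm2, Mef2d and Bin1 were chosen after their values were seen.

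Within the isoform list, Prkag1, Myl6, Myo18a, Tpm4, Naca and Pdlim5 each exchanged a chain that held 100% of the gene's FPKM in 1 of the libraries compared. That chain was annotated in Pdlim5 alone, and Prkag1 and Tpm4 did not change at a shared splice site. Rbfox2 changed by -89.6 percentage points at 60 h against growth and Ldb3 by -85.6 at 168 h against 120 h. Tpm1 changed by 95.2 and Trip10 by 80.7 points at 168 h against growth. Growth stood apart from the other 3 libraries in splice site choice in 23 of 51 isoform-list genes, and the 60 h, 120 h and 168 h libraries in 1, 3 and 5. Over all 2977 genes with a choice, these numbers were 290, 126, 177 and 183. Chain switches were found in 1547 of 3983 genes at 60 h against growth, 1768 of 4102 genes at 120 h against 60 h, 1810 of 4125 genes at 168 h against 120 h and 1802 of 3873 genes at 168 h against growth. Of these 705, 730, 744 and 822 also changed at a shared splice site. Among isoforms found in at least 2 libraries, switches were found in 672 of 2548, 739 of 2632, 673 of 2515 and 836 of 2403 genes. Of genes with a change of 100 points, the 10 with the most FPKM in the lower library included Myl4, Rpl41, Ldha, Cd63, Rplp0, Eif4ebp1, Eef1b2 and Eif3h, and of these 10 Eif3h alone changed at a shared splice site. Rpl41, Cd63, Rplp0, Eif3h and Tpm4 are uncertain, with 18.5%, 12.3%, 36.5%, 25.0% and 13.8% of their words in other genes.

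First exons, taken by their first splice donor, switched in 893 of 2182 genes at 60 h against growth, 1113 of 2371 genes at 120 h against 60 h, 1126 of 2379 genes at 168 h against 120 h and 1059 of 2162 genes at 168 h against growth. In the isoform list they switched in 18 of 32, 14 of 35, 14 of 38 and 22 of 36 genes. Over all genes with annotated first donors alone, they switched in 319 of 1010, 345 of 1013, 309 of 968 and 354 of 952 genes. These are switches of the first donor assembled. Where an assembled transcript lacks its start, that donor is internal, so a switch need not be a change of first exon. With all first donors, switches were found in 40.9% of genes at the first step and in 46.9% and 47.3% at the later steps. Myl4, Rpl41, Tnnt1, Cd63, Tmbim6, Akt1, Rps15, Pcbp2, Map4 and Prdx1, chosen in the same way, changed by 100 percentage points in at least 1 comparison, as did Prkag1, Myl6 and Mtmr3 within the list. In the comparisons for which they were chosen, Rps15 and Map4 alone of all these genes also changed at a shared splice site. At 60 h against growth Myo18a changed by -84.0 points, Tpm3 by -76.3 and Tead1 by 70.2. At 120 h against 60 h Macf1 changed by 69.9 points, Ldb3 by 63.6 and Pkm, a pyruvate kinase gene, by 59.3. Rps15, Tpm3 and Pkm are uncertain, with 23.7%, 25.1% and 25.9% of their words in other genes.

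**Figure D3:**
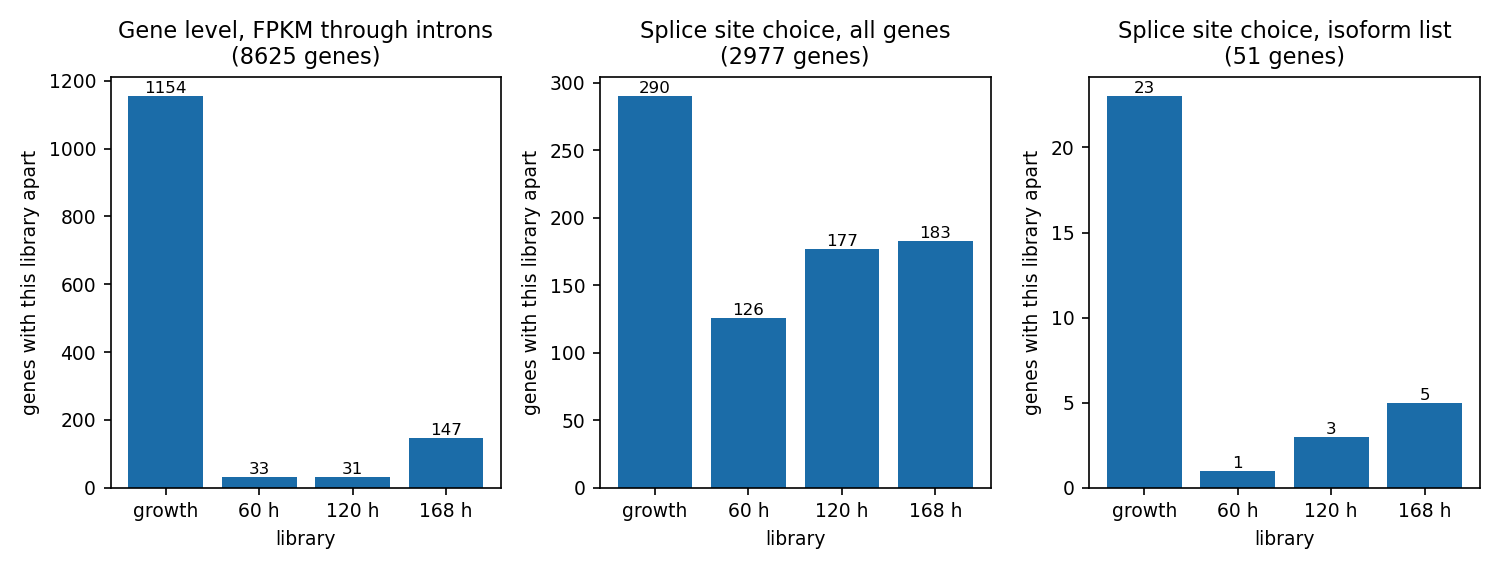
Number of genes, on bars from 0, in which 1 library stands apart from the other 3, for FPKM through the introns in 8625 genes, splice site choice in 2977 genes and splice site choice in 51 genes of the isoform list. The growth library has the highest bar in each panel, at 1154, 290 and 23 genes.

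**Figure D4:**
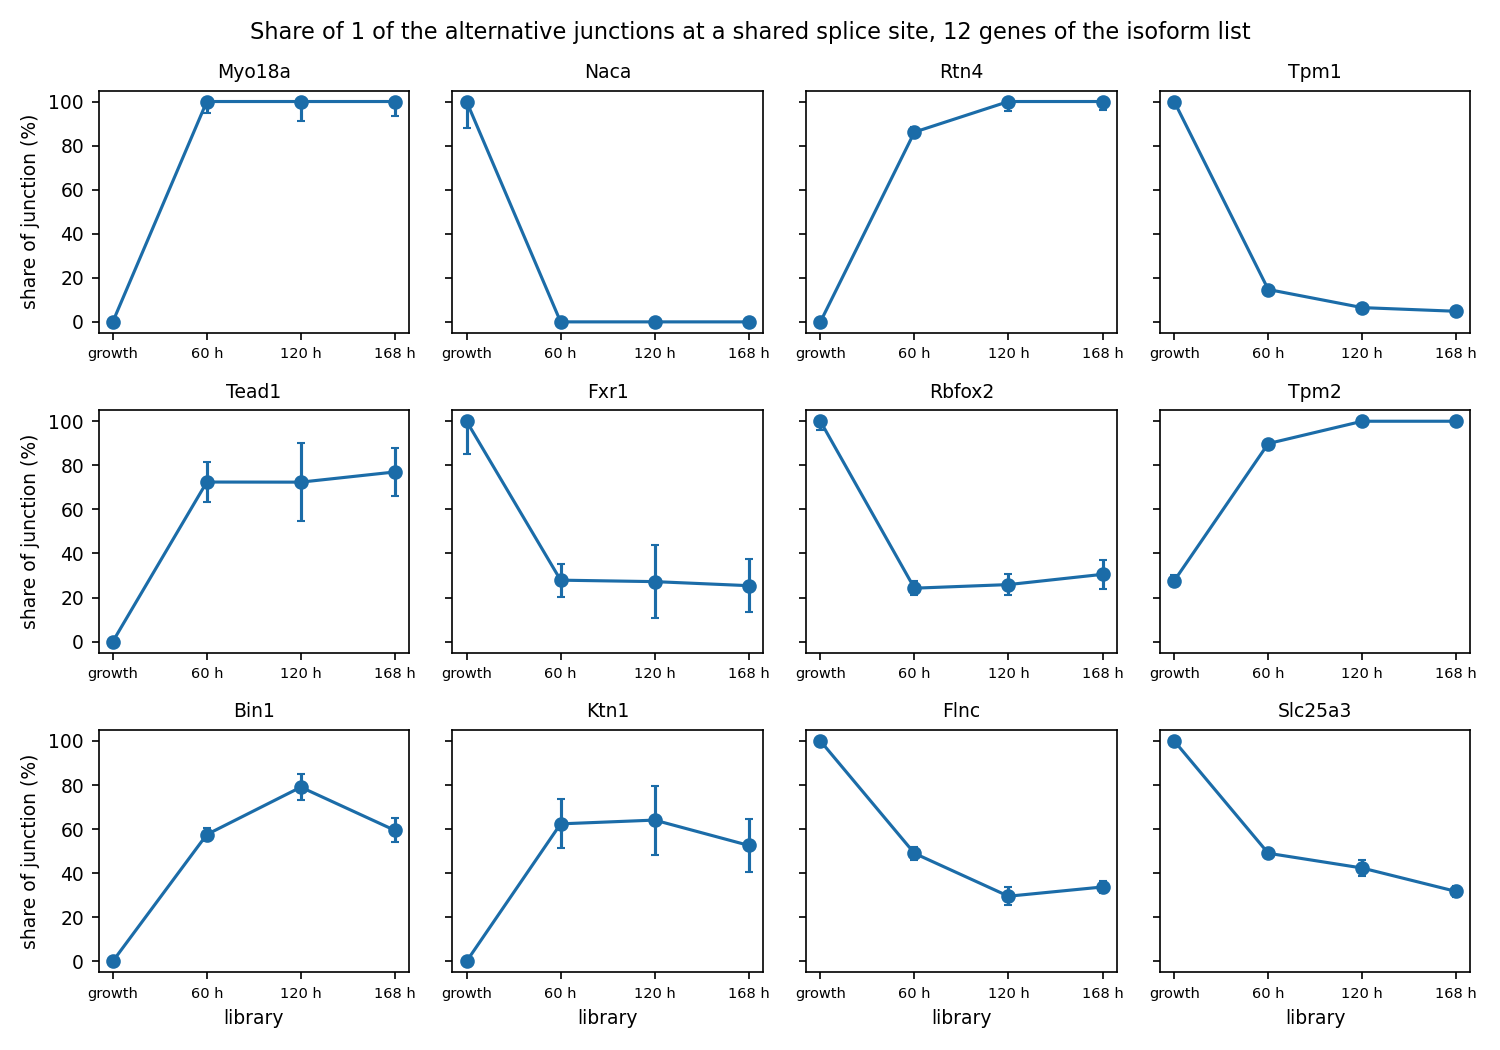
Share, in percent, of 1 junction among the alternatives at a shared splice site in the growth, 60 h, 120 h and 168 h libraries for the 12 isoform-list genes, of 23 with the growth library apart, whose growth share lay farthest from the others; points are single libraries and bars run to the confidence limits, kept within 0 and 100. Tpm1 goes from 100% in growth to 4.80% at 168 h, and Tpm2 from 27.6% to 100%.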

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

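The 3 tests on isoform switches were chosen after the counts they use were seen, and the measure through the introns was added after seeing the data. The other 5 tests in this part were chosen before their results were seen.

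Signal outside the comparisons appeared in every library. Single-exon transcripts outside named genes took 10%, 8.01%, 8.23% and 7.64% of assembled fragments in growth and at 60 h, 120 h and 168 h. Multi-exon transcripts without a gene name took 1.09%, 1.55%, 1.30% and 1.06%. No control library gives a background for these values. Part of this signal lay over genes. In growth, 1 such transcript at 1270 FPKM covered the whole span of Ftl1 on chromosome 7, a gene uncertain for its copies.

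Some genes had no value through the introns in 1 library although both neighbouring time points held them at 20 FPKM or more. They were 2 of 2467 genes at 60 h and 13 of 2667 at 120 h, among them Ndufa5 at 60 h and Rpl8, Tnnt3, Zbed5, Tnfaip2 and Dpm3 at 120 h. Single-exon pieces lay within the span of 20.0% of these 15 genes in the library without them and of 6.67% in each neighbour, a ratio of 300%. The pieces are too few for an interval, so a locus left out by the assembly and a gene switched off in that culture cannot be told apart for these genes. Genes with copies were 2.07 times as frequent as at matched levels, with an interval from 0 to 5.17, so shared reads stay open too.

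At 120 h against 60 h more genes rose than fell by the sum, 1556 against 485. The tables argue against a rise of these genes. For the 1377 called higher and assembled in both libraries, the median log2 ratio of a gene's share of the library's fragments was 0.0128, with an interval from -0.0218 to 0.0544. Of the 1144 genes called higher by the sum and not through the introns, 93.8% had more assembled transcripts at 120 h, against 29.1% of 9950 genes not called. Choosing genes by the sum and against the introns largely sets that percentage, so it does not bear on whether pieces of a gene were counted more than once. The unchanged share of fragments does bear on it, since the sum of the same genes rose at least 2-fold. Over the union of exons 272 genes rose and 572 fell. Counting pieces more than once would give these values, but shorter assembled transcripts were not separated from it.

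Over all genes with enough expression, isoform switches were found in 38.8% at the first step and in 43.1% and 43.9% at the later steps, but in the isoform list the shares were 57.6%, 45.3% and 43.8%. The shallowest library did not hold the most genes apart in splice site choice, having 0.610 times the number of the growth library, the highest. Among the later libraries the numbers were 126 at 60 h, 177 at 120 h and 183 at 168 h. A part for depth stays open, since growth can differ for other reasons. Of the switches at 60 h against growth 45.6% held a change at a shared splice site, so different ends and breaks of assembled transcripts may give many of the others. Growth had 1.58 times the next highest number of genes apart, close to the bound of 1.5 set for it, which is weakly consistent with a difference in splice site choice between growth and later times. With 1 library per time point, such a difference and a peculiarity of the growth library were not separated.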

How the results depend on the processing

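Tests with the measures through the introns and over the union of exons, genes assembled in both libraries, shared splice sites, equal totals for lists and 1 library apart were chosen after seeing the data. No paired analysis was possible because each time point has 1 library. Of 104 counts under settings fixed beforehand, 59 stayed within 1.5 times the main count, as did 20 of 40 under added settings. Of 252 list medians under fixed settings, 236 kept their sign and their place inside or outside the central 95% of random lists, 5 newly lay outside it and 3 no longer did, while 8 changed sign. Under added settings these numbers, of 252, were 193, 18, 8 and 33. Of 16 medians of lists written later, 15 kept both through the introns. Dropping the minimum FPKM changed no count, since a 2-fold change with a pseudocount of 1 already needs 1 FPKM. Depth limits the 120 h library most, where 1321 genes had under 20 fragments. Stricter limits lower counts by construction, and otherwise the cause was not tested.

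Under the 4-fold rule, higher and lower counts were 505 and 302 at 60 h against growth, 215 and 157 at 120 h against 60 h, 148 and 190 at 168 h against 120 h, and 700 and 611 at 168 h against growth. By that rule 1236 genes passed at any step, 659 at the first alone. Loci without the annotation gave 2279 higher at 60 h against growth, 1317 lower at 120 h against 60 h and 1244 higher at 168 h against 120 h. For genes assembled in both libraries these counts were 865, 241 and 279. The 120 h lower and 168 h higher counts were 316 and 327 with at least 5 FPKM, and 893 and 803 with equal totals. Multi-exon transcripts alone gave 860 higher at 120 h. Through the introns 507 were higher and 931 lower at 120 h against 60 h, and 812 and 621 at 168 h against 120 h. Over the union of exons 1283 were lower at 60 h, 272 higher at 120 h and 335 lower at 168 h against 120 h.

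The median of the insulin-like growth factor axis at 60 h reversed to -0.0115 for members with at least 1 FPKM. That of osteoblast and chondrocyte markers at 120 h against 60 h reversed to -0.0703 through the introns and -0.133 over the union of exons, and at 168 h against 120 h to 0.02055 over the union. That of isoform genes at 168 h against growth reversed to -0.0554 through the introns. With contained chains counted as the same, 15770 chains lay in 1 library, 9244 in 3 and 13191 in 4.

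Medians that lay inside the central 95% changed sign as follows. Through the introns and over the union of exons at 60 h, splicing regulators went from 0.03 to -0.28 and -0.31, interferon response from -0.19 to 0.54 and 0.46 and adipocyte markers from -0.29 to 1.15 and 1.16. By these measures at 120 h against 60 h, myogenic regulators went from 0.23 to -0.14 and -0.30, the last at percentile 2.45, serum response from 0.07 to -0.03 and -0.22 and interferon response from 0.44 to -0.13 and -0.11. Over the union alone, cell cycle exit went from 0.28 to -0.09 and isoform genes from 0.16 to -0.03. With median-ratio rescaling and equal totals, extracellular matrix went from 0.12 to -0.07 and -0.10, serum response from 0.07 to -0.10 and -0.14 and isoform genes from 0.16 to -0.02 and -0.05, and with equal totals proteasome and heat shock went from 0.18 to -0.03. At 168 h against 120 h, through the introns and over the union, proteasome and heat shock went from 0.00462 to -0.04 and -0.15, the last at percentile 2.22, interferon response from 0.01 to -0.03 and -0.06 and cardiac markers from -0.13 to 0.09 and 0.34. Through the introns alone the sarcomere went from 0.06 to -0.02, and isoform genes went from -0.11 to 0.01 and 0.04 through the introns and with median-ratio rescaling. For members with at least 1 FPKM, macrophage and endothelial markers went from -0.12 to 0.52 at 120 h against 60 h and from 0.14 to -0.77 at 168 h against 120 h. At 168 h against growth, cardiac markers went from -0.03 to 0.12, 0.61 and 0.42 with median-ratio rescaling, through the introns and over the union, and ribosomal protein genes from 0.21 to -0.24 over the union.

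In the order of the 4 comparisons, isoform switches numbered 926, 1060, 1130 and 1104 at 50 percentage points, 481, 522, 568 and 542 at 20 FPKM, 672, 739, 673 and 836 for isoforms in at least 2 libraries, and 775, 784, 800 and 891 at shared splice sites. First exon switches numbered 483, 625, 628 and 591 at 50 points, 252, 298, 307 and 301 at 20 FPKM, and 319, 345, 309 and 354 with annotated first donors. By the summed FPKM, genes with 1 library apart numbered 129 at 60 h and 123 at 120 h among genes in all 4 libraries, and 1839, 297, 407 and 414 in growth and at 60 h, 120 h and 168 h among all genes.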

Other observations

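The tests on the 8 gene lists in this part, and the genes named from them, were chosen after the comparisons had been seen. Trib3, Ddit3, Atf3, H19, Igf2, Cdkn1c and Igf2r also stand in lists fixed beforehand. Of amino acid stress response genes 10 of 19 rose and 0 fell at 60 h against growth (median log2 ratio 1.07, percentile 100.0, and 1.25 through the introns). Asns, the asparagine synthetase gene, rose from 98.1 ± 5.72 to 297 ± 9.29 FPKM and Ddit3 from 11.4 ± 1.77 to 87.2 ± 3.03. The amino acid transporter genes Slc7a5 and Slc3a2 rose from 99.6 ± 2.72 to 402 ± 4.65 and from 135 ± 4.50 to 439 ± 4.35 FPKM. At 168 h against growth 8 of 19 rose and 0 fell (median log2 ratio 0.70, percentile 99.9). Of Notch pathway genes 4 of 12 rose and 2 fell at 60 h (median log2 ratio 0.74, percentile 100.0), and 6 rose and 1 fell through the introns. The fall of Notch2 did not pass the rule through the introns or over the union of exons, at -0.24 in both. Nor did it pass after median-ratio rescaling, at -0.99. Notch3 rose from 10.4 ± 0.428 to 51.6 ± 0.729 FPKM, Heyl, a Notch target gene, from 8.14 ± 2.43 to 22.1 ± 0.655 (0.701 in growth through the introns) and Hes6 from 54.0 ± 2.30 to 128 ± 2.75. Lfng fell from 13.7 ± 0.912 to 1.79 ± 0.255 FPKM. At 168 h against growth 3 of 12 rose and 1 fell (median log2 ratio 0.25, percentile 92.5).

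Of lysosome and autophagy genes 3 of 22 rose and 4 fell at 60 h (median log2 ratio 0.29, percentile 99.4). Of those 4, Ctsb, Npc2 and Bnip3 did not pass the rule over the union of exons, with log2 ratios of -0.20, -0.51 and 0.38. The other, Atg7, was not assembled at 60 h. At 168 h against growth 9 of 22 rose and 1 fell (median log2 ratio 0.85, percentile 100). Map1lc3a, an autophagosome gene, rose from 47.4 ± 2.67 to 511 ± 15.0 FPKM, Ctsd, the cathepsin D gene, from 279.6 ± 5.37 to 983 ± 7.03 (uncertain, with 36.6% of its words in other genes) and Gaa, the acid alpha-glucosidase gene, from 25.9 ± 2.28 to 114 ± 1.73. Npc2 fell from 397 ± 6.41 to 104 ± 1.71 FPKM, and its log2 ratio of -0.78 over the union of exons did not pass the rule. Of cholesterol synthesis genes 4 of 20 rose and 0 fell at 60 h (median log2 ratio 0.42, percentile 99.9), and 3 of 20 rose and 6 fell at 168 h against growth (median log2 ratio -0.70, percentile 1.60). Through the introns these counts were 3 and 0, and 3 and 8. The rises of Fdps and Fdft1 at 60 h did not pass the rule through the introns, at -0.32 and 0.62. Sc5d, which rose in both comparisons, was not assembled in growth. At 168 h Fdft1 rose by the sum and was called lower through the introns, where it had no value. Cyp51 fell from 42.6 ± 1.29 to 18.4 ± 0.697 FPKM, with a log2 ratio of -0.97 after median-ratio rescaling, which did not pass the rule, and Msmo1 from 40.8 ± 1.76 to 13.8 ± 0.832. Of oxidative phosphorylation genes 1 of 31 rose and 1 fell at 60 h (median log2 ratio 0.18, percentile 99.1), and 4 of 31 rose and 0 fell at 168 h (median log2 ratio 0.45, percentile 99.4). The rise of Cox5b did not pass the rule over the union of exons, at 0.30 at 60 h and 0.53 at 168 h. Uqcrh, which fell at 60 h, had a log2 ratio of -1.02, close to the bound of the rule. Of mitochondrial ribosome genes 0 of 23 rose and 1 fell at 60 h (median log2 ratio -0.31, percentile 31.8), and 0 of 23 rose and 4 fell at 168 h (median log2 ratio -0.54, percentile 4.91). After median-ratio rescaling the fall of Mrpl1 at 60 h did not pass the rule, at -0.92. Nor did those of Mrpl18 and Mrps22 at 168 h, at -0.94 and -0.87. Of imprinted genes 3 of 11 rose and 1 fell at 60 h (median log2 ratio 0.37, percentile 97.7, and 88.2 through the introns), and 3 of 11 rose and 2 fell at 168 h (median log2 ratio -0.25, percentile 35.5). Of histone genes 0 of 4 rose and 1 fell at 60 h (median log2 ratio -0.76, percentile 8.60), and 0 of 4 rose and 1 fell at 168 h (median log2 ratio -0.46, percentile 26.5). The list had 12 members, and these values describe only the 4 measured, H2afz, H2afv, H3f3b and H2afy. Genes with a single exon were not analysed. H2afz, which fell at 60 h, did not pass the rule after median-ratio rescaling, at -0.96.

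Transcripts on the mitochondrial chromosome took 0.419%, 0.519%, 0.876% and 0.526% of assembled fragments in growth and at 60 h, 120 h and 168 h. In growth, at 60 h and at 168 h 1 transcript, from 10956 to 16284 in growth, held all of this share. At 120 h the transcript at that place held 0.385%. Others, from 52 to 5134 and from 5319 to 6760, held 0.282% and 0.209%, so the 120 h value counts different transcripts.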
